A study of Homo sapiens with 6 samples.

How the data were processed

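Total RNA of MDA-MB-468 cells was sequenced in 3 untreated samples and 3 samples given 100 µM DETA/NO for 10 days. The 6 deposited files hold 1 normalized read count (signal) per gene, 45019 rows each. Per the submitters' processing notes, the tools were FastQC 0.11.9, MultiQC 1.14, TopHat2 2.1.1, Bowtie2 2.5.0.0, deepTools 3.5.1, Subread, featureCounts 2.0.3, DESeq2 1.38.3 and R 4.2.2, with the GRCh38 build. The annotation and counting settings were not given in the sources used here. In each library 100% of values above 0 were a whole number of reads times 1 factor (tolerance 0.01), so whole reads were recovered.

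Groups came from the sample titles. The files of DETA/NO replicates 1 and 2 were identical in every value and were averaged and counted once, and a header inside both named the same library. The depth was 28897422 to 34637343 recovered reads per library. In every file 27 row names had turned into dates. They held 0.246% of reads, were kept in the tests and are not named.

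The main test was limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust eBayes, on log2(value + 1), for genes with a mean value of at least 10. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A fold change is on the log2(value + 1) scale and understates the change of low genes. The unit, a normalized count, is why a test on log values was used, as set before the data were examined. edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, other scalings, pseudocounts and filters, a replicate block, and leaving out each library were alternatives. Counts of list genes without each library and list tests without the GC and length trends were added after seeing the data. The tests were checked on simulated counts for DETA/NO against untreated (16409 genes, 50 changed at each size): limma recovered 70% of genes changed 1.5-fold, 94% at 2-fold, 98% at 4-fold and 100% at 8-fold, with 11 false among 192 calls. Python 3.11.15, pandas 2.3.3 and scipy 1.17.1 were used for the other steps.

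There were 38 gene lists, fixed before the data were examined, and lists with at least 5 tested genes were tested with camera (preset correlation 0.01) and fry. Of the list genes, 73 were at 0 in every library and 128 in all lay under the filter. The named genes were fixed by rule before the data were examined: the 10 largest rises and 10 largest falls with adjusted p under 0.05, a mean of at least 100 in the higher group and separated libraries; from each list with a called gene, up to 2 rising and 2 falling genes with the smallest adjusted p; FTO, ALKBH5, METTL3, METTL14, WTAP, HMOX1, NOS2, GAPDH, ACTB, EGFR and TFRC always; and up to 4 genes of each list that passed camera. Positions are from GENCODE release 29 (GRCh38). A gene is named here with the share of its span that other genes overlap where that share is large. The labels do not say whether replicate numbers mark a shared day. The value of 1 gene of the lists is not reported here.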

Results

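Total RNA was sequenced from MDA-MB-468 cells, an established basal-like, triple-negative breast cancer line with an amplified EGFR gene. One group was left untreated and the other received 100 µM DETA/NO, a compound that releases nitric oxide slowly in culture, for 10 days. Per the labels, cells were replated every 48 h and left to adhere for 4 h before the compound was added again. The series asks whether nitric oxide, which its submitters describe as an inhibitor of the m6A demethylase FTO, goes together with changes in transcription. Each group had 3 labelled samples. The files of DETA/NO replicates 1 and 2 held identical values and were counted as 1 library, so that n = 3 untreated and n = 2 DETA/NO libraries. The labels do not say that the samples came from separate cultures, and p-values measure only the spread between these libraries.

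Recovered read totals were 33297603, 32872785 and 34637343 in the untreated libraries. They were 28897422 in the shared DETA/NO library 1 and 2 and 34210950 in DETA/NO library 3. Between 22374 and 22614 genes had a value above 0 in each library. Pearson correlations of log2 values across genes were 0.9957 to 0.9958 among untreated libraries, 0.9956 between the DETA/NO libraries and 0.985 to 0.987 between groups. The first principal component held 67.3% of the variance.

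DETA/NO went with higher values of INHBA, IL7R, CYP1A1 and interferon-stimulated genes, and with lower values of CP, KIT, TF and genes of cholesterol synthesis. With an estimated correlation neither list passed camera (adjusted p = 0.377 for both). Fry gave adjusted p of 0.0204 for the interferon list and 0.0177 for the cholesterol list. When 1 untreated library was left out, 7 or 8 of the 20 interferon-stimulated genes passed. With all libraries, both DETA/NO libraries lay above every untreated library in all 20. Of 16409 genes tested with limma at a Benjamini-Hochberg adjusted p of 0.05, 3565 were higher and 3555 lower, together 43.4%. Most changes were small: 362 genes were higher and 259 lower by at least 2-fold. In 10045 genes (61.2%) the DETA/NO libraries lay on 1 side of all untreated libraries, where chance gives 20%. Limma without both the trend and the robust option called 2262 genes higher and 2497 lower, and of the genes named below ALKBH5, METTL14, DNAJB1, HSP90B1, NUPR1, TRIM29, ESR1, PKM, ATG7 and TFRC then lost the call. The median log2 fold change of all tested genes was -0.00016, and it lay between -0.0103 and -0.00342 under other scalings.

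Among the largest rises, INHBA, which encodes a subunit of activin A, went from 844 ± 79.3 (SD, n = 3) to 5917 ± 253 (SD, n = 2) normalized reads, a log2 fold change of 2.81 ± 0.064 (SE; adjusted p = 5.41e-13). INHBA lies on chromosome 7 at 41667168 to 41705834 (GRCh38). CYP1A1, a cytochrome P450 on chromosome 15 at 74719542 to 74725610, went from 37.5 ± 6.87 to 301.8 ± 10.4 (log2 fold change 2.99 ± 0.164). IL7R, the alpha chain of the interleukin 7 receptor, rose by 2.71 on the log2 scale. MYO7B, SYT14 and MYH15 rose by 3.07, 2.94 and 2.90. COL17A1, a hemidesmosome collagen, rose by 2.59 from a low level of 18.5 ± 3.90.

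The largest fall was that of CP, the copper-carrying ferroxidase ceruloplasmin, from 6049 ± 13.5 to 1204 ± 16.4 normalized reads (log2 fold change -2.33 ± 0.036, adjusted p = 1.58e-30). CP lies on chromosome 3 at 149162410 to 149222055. TF, the iron carrier transferrin, had a log2 fold change of -1.70 ± 0.075. KIT, a receptor tyrosine kinase, went from 343 ± 18.6 to 85.6 ± 21.6 (log2 fold change -2.01). GABRP, KIAA1324, POU2AF1, CYP4Z1, C8orf31, SOSTDC1 and COLCA2 had log2 fold changes from -2.14 to -1.71. Other genes' spans covered 64% of COLCA2, 50% of GABRP, 46% of TF, 45% of CYP4Z1 and of IFI6, and 31% of INHBA, and reads in such spans are uncertain.

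**Figure D1:**
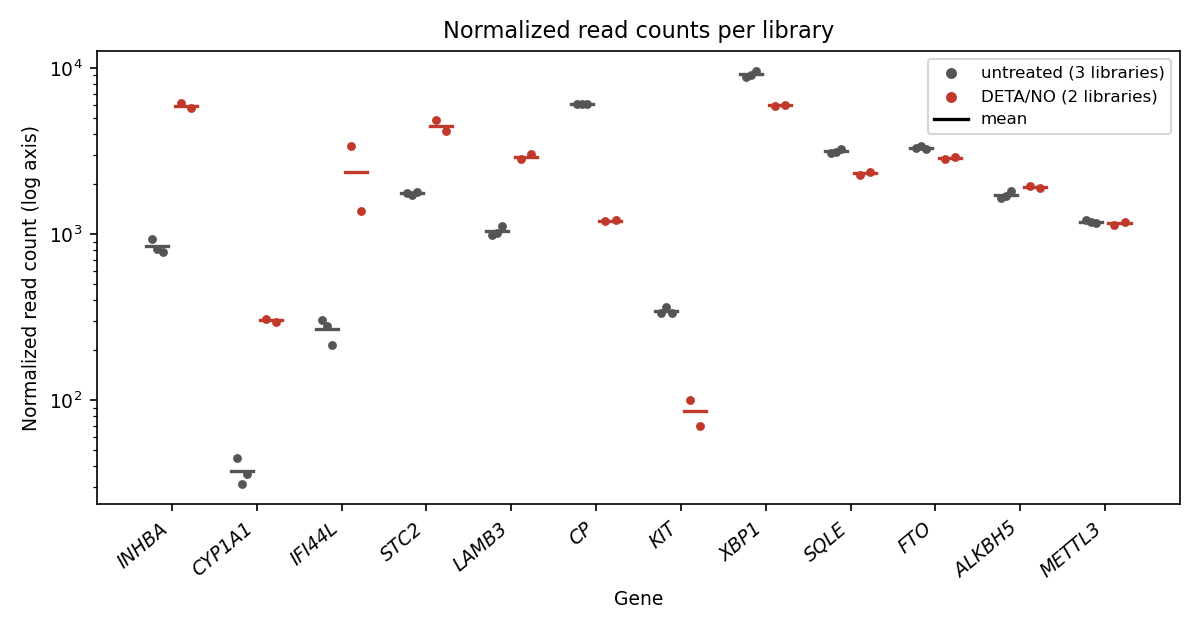
Normalized read counts (log axis) of 12 genes in each library, with untreated libraries in grey, DETA/NO libraries in red and horizontal lines for group means. INHBA went from 844 to 5917 and CP from 6049 to 1204, while the METTL3 means were 1183 and 1162.

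Genes of the m6A machinery changed by small amounts. FTO on chromosome 16 (53701692 to 54158512) went from 3294 ± 71.9 to 2867 ± 45.7, a log2 fold change of -0.20 ± 0.037 (adjusted p = 4.37e-05). The other demethylase, ALKBH5, went from 1718 ± 93.1 to 1922 ± 48.8 (log2 fold change 0.16 ± 0.047, adjusted p = 0.00489), and without the shared DETA/NO library 1 and 2 its adjusted p was 0.0649. The methyltransferase METTL3 had 1183 ± 24.1 and 1162 ± 31.9 (adjusted p = 0.707). METTL14, its partner, had a log2 fold change of -0.13 (adjusted p = 0.039), with an adjusted p of 0.302 without DETA/NO library 3, 0.121 and 0.0622 without untreated libraries 2 and 3, 0.0589 without a filter, and 0.137 in DESeq2. WTAP, with 100% of its span overlapped, was listed at 0 in every library, which may not speak to its expression. Of 11 tested m6A writers, 3 rose and 2 fell. Without DETA/NO library 1 and 2, 1 rose, and 1 fell without that library, DETA/NO library 3 or untreated library 2 or 3. The writer list did not pass camera (adjusted p = 0.961). Of 12 readers, 7 rose, such as IGF2BP2 (0.45) and YTHDF1 (0.19), and 2 fell, among them RBMX (-0.17), with 1 falling without untreated library 1 or 2 or DETA/NO library 1 and 2. The reader list had an adjusted p of 0.0760 in camera and 0.0161 in fry, and of 0.0465 in camera without untreated library 2. Among genes with GC and length values it had 0.106 before and 0.0408 after those trends were removed, and 4 of its genes rose without DETA/NO library 3. Of 19 tested iron-dependent histone and DNA demethylases, 4 rose and 3 fell, KDM5B by 0.14 upward and TET1 by -0.48 (camera adjusted p = 0.823), and 2 rose without DETA/NO library 3.

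Camera with a preset correlation of 0.01 found 10 of 34 lists higher and 5 lower than other genes. None passed with an estimated correlation, and that adjusted p stands beside each list. Correlation need not be the whole reason. The estimate was 0.92 for interferon-stimulated genes but -0.048, below the preset, for EGFR ligands and MAPK feedback genes. For the latter the unadjusted camera p still went from 4.4e-09 to 0.0078. Fry, which does not compare a list with other genes, passed 13 lists higher and 5 lower. Of the lists past camera, it did not pass endoplasmic reticulum chaperones or luminal genes. All list counts were also "adjusted over the list alone".

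**Figure D2:**
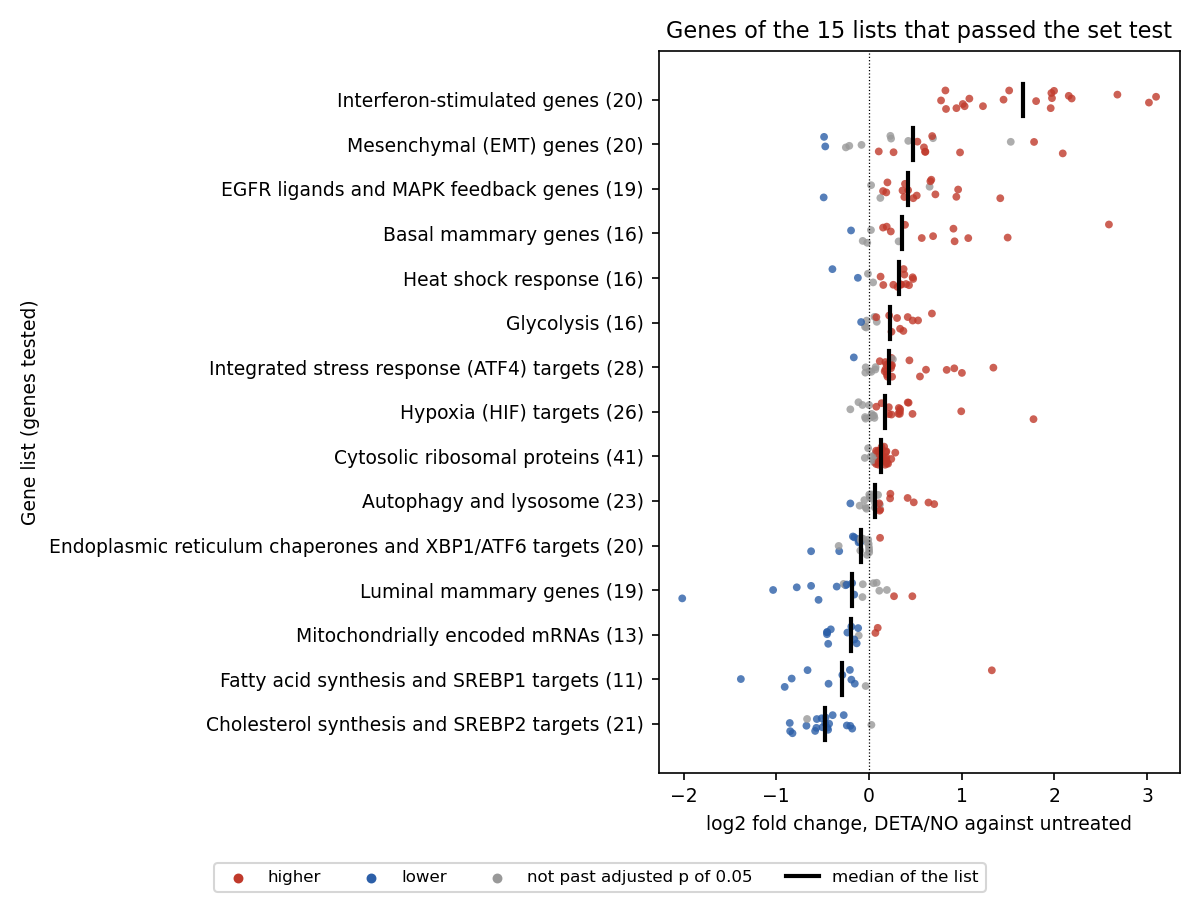
Log2 fold changes (x axis, DETA/NO against untreated) of each tested gene in the 15 lists that passed camera, with genes that rose in red, genes that fell in blue, others in grey and black bars for list medians. The median was 1.66 for interferon-stimulated genes and -0.47 for cholesterol synthesis.

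All 20 tested interferon-stimulated genes rose, 20 also when adjusted over the list alone, and 16 of them by at least 2-fold (median log2 fold change 1.66, camera adjusted p = 5e-18; adjusted p = 0.377 with an estimated correlation). IFI44L had 304, 281 and 214 normalized reads in the untreated libraries, against 3364 in DETA/NO library 1 and 2 and 1367 in library 3. IFI27 rose by 3.10, IFI6 by 2.68, HERC5 by 1.96 and OASL by 1.80 on the log2 scale. Both DETA/NO libraries lay above all untreated libraries in all 20 genes, and the 2 libraries differed by a median of 0.75 on the log2 scale. Without untreated replicate 1, 2 or 3, 8, 7 and 7 of the 20 genes passed. The rises themselves changed little in 2 genes that lost the call. In the same order, IFI6 then rose by 2.76, 2.65 and 2.63 on the log2 scale, and IFI44L by 3.12, 3.07 and 2.87. Over the untreated mean, the median log2 rise of the 20 genes was 2.02 in DETA/NO library 1 and 2 and 1.34 in library 3. IFI44L had adjusted p of 0.020 with all libraries and 0.0769, 0.0828 and 0.0737 without each untreated library in turn; IFI6 had 0.0136, then 0.0594, 0.0678 and 0.0596.

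Targets of the integrated stress response factor ATF4 rose in 20 of 28 genes and fell in 1, NUPR1 (21 and 1 adjusted over the list alone; camera adjusted p = 4.29e-08; adjusted p = 0.377 with an estimated correlation). NUPR1 had an adjusted p of 0.127 without DETA/NO library 3, where 0 fell. STC2, a secreted glycoprotein, went from 1765 ± 36.7 to 4490 ± 498. CTH, an enzyme of cysteine synthesis, rose by 1.00, and the amino acid transporters SLC7A5 and SLC3A2 by 0.62 and 0.55. Of 16 heat shock genes, 12 rose and 2 fell (12 and 2 adjusted over the list alone; camera adjusted p = 1.9e-05; adjusted p = 0.351 with an estimated correlation). HSPH1 rose by 0.47, STIP1 by 0.37 and HSPA8 by 0.31, and DNAJB1, with 85% of its span overlapped, had a log2 fold change of -0.12, with an adjusted p of 0.0895 without DETA/NO library 1 and 2, where 1 fell. Endoplasmic reticulum chaperones fell in 7 of 20 genes and rose in 1, HSP90B1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0257; adjusted p = 0.539 with an estimated correlation). Without DETA/NO library 3, 11 fell, and without library 1 and 2, 5 fell and 3 rose. HSP90B1 had a log2 fold change of 0.12, and of 0.07 under quantile normalization. XBP1 had a log2 fold change of -0.62 and CRELD2 of -0.32. Without the shared DETA/NO library 1 and 2 that list had an adjusted p of 0.237, and fry gave 0.0573.

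Cholesterol synthesis genes and other SREBP2 targets fell in 19 of 21 tested genes and rose in 0 (20 and 0 adjusted over the list alone; median log2 fold change -0.47, camera adjusted p = 1.4e-13; adjusted p = 0.377 with an estimated correlation). MSMO1 went from 4591 ± 261 to 3240 ± 56.4, SQLE from 3143 ± 87.0 to 2316 ± 84.7, and FDFT1 had a log2 fold change of -0.39. Fatty acid synthesis genes fell in 9 of 11 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00013; adjusted p = 0.377 with an estimated correlation), including PNPLA3 (-0.66) and ACLY (-0.19), while ELOVL6, an elongase, rose by 1.33.

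Ligands of EGFR and feedback genes of the MAPK pathway rose in 15 of 19 genes and fell in 1, SPRY1 (16 and 1 adjusted over the list alone; camera adjusted p = 4.29e-08; adjusted p = 0.265 with an estimated correlation). ETV5 rose by 0.96, SPRY2 by 0.94 and HBEGF by 0.66. EGFR itself went from 222201 ± 4474 to 246909 ± 1529 (log2 fold change 0.15). Under quantile normalization it was at 0 change, which that scaling gives to any gene of the same rank in every library. Basal mammary genes rose in 11 of 16 and fell in 1, TRIM29 (12 and 1 adjusted over the list alone; camera adjusted p = 2.2e-06; adjusted p = 0.377 with an estimated correlation), with LAMB3 higher by 1.50. TRIM29 had adjusted p of 0.102 without DETA/NO library 1 and 2, where 0 fell, 0.0637 in DESeq2 and 0.0538 under TMM scaling. Luminal genes fell in 10 of 19 and rose in 2, GATA3 and ESR1 (10 and 2 adjusted over the list alone; camera adjusted p = 0.0075; adjusted p = 0.539 with an estimated correlation and 0.0802 in fry). ESR1 had an adjusted p of 0.104 without DETA/NO library 3, where 1 rose, while 4 rose without library 1 and 2 and 5 without untreated library 3. AGR2 had a log2 fold change of -1.03 and MUC1 of -0.54. Mesenchymal genes rose in 10 of 20 and fell in 2, FN1 and CCN2 (10 and 2 adjusted over the list alone; camera adjusted p = 0.00085; adjusted p = 0.351 with an estimated correlation). Of 4 tested fibroblast markers 3 rose, with a list median of 0.32 (4 rose adjusted over the list alone). CCN2 had an adjusted p of 0.0766 without untreated library 3, where 1 mesenchymal gene fell. THBS1, with 64% of its span overlapped, rose by 2.09, TGFBI by 1.78 and LOXL2, with 54% overlapped, by 0.98. Of 22 epithelial genes, 6 rose and 5 fell (camera adjusted p = 0.967), but 3 rose without DETA/NO library 3 and 3 fell without library 1 and 2.

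Hypoxia targets rose in 15 of 26 genes and fell in 0 (15 and 0 adjusted over the list alone; camera adjusted p = 0.0001; adjusted p = 0.351 with an estimated correlation). CA9, a carbonic anhydrase, went from 198 ± 29.8 to 676 ± 5.95, and ADM rose by 1.00. Glycolysis genes rose in 10 of 16 and fell in 1, PKM (11 and 1 adjusted over the list alone; camera adjusted p = 0.00068; adjusted p = 0.377 with an estimated correlation), with PFKP higher by 0.68 and LDHA by 0.42. PKM had adjusted p of 0.196 without DETA/NO library 1 and 2 and 0.0593 without untreated library 2, where 0 fell. Mitochondrially encoded mRNAs fell in 10 of 13 genes and rose in 2 (10 and 2 adjusted over the list alone; camera adjusted p = 4.2e-05; adjusted p = 0.377 with an estimated correlation). Without DETA/NO library 3 or untreated library 1, 0 rose, and without untreated library 2, 1 rose. MT-CYB had a log2 fold change of -0.45, and of -0.30 under quantile normalization. Those mRNAs held 7.92% ± 0.131 of the values in untreated libraries (SD, n = 3) and 6.80% and 7.17% in the DETA/NO libraries, while the 45S ribosomal precursor held 0.284% ± 0.0273 and 0.393% and 0.396%. The exact two-sided permutation p, taken as the doubled 1-sided share, was 0.2 for both. That is the smallest that this doubling allows with 10 arrangements. Ribosomal protein genes rose in 31 of 41 and fell in 0 (32 and 0 adjusted over the list alone; median 0.13; camera adjusted p = 3.4e-07; adjusted p = 0.377 with an estimated correlation), RPL8 by 0.24, and 19 rose without DETA/NO library 3. Autophagy and lysosome genes rose in 9 of 23 and fell in 1, ATG7 (9 and 1 adjusted over the list alone; camera adjusted p = 0.019; adjusted p = 0.377 with an estimated correlation), GABARAPL1 by 0.64. ATG7 had a log2 fold change of -0.20, and of -0.10 without DETA/NO library 1 and 2 (adjusted p = 0.242), where 0 fell.

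Other lists did not pass camera. NRF2 targets rose in 9 of 27 genes, such as FTH1 (0.61, with 73% of its span overlapped), and fell in 12, such as AKR1C2 (-0.83; adjusted p = 0.257). HMOX1, the haem oxygenase, went from 369 ± 14.1 to 456 ± 7.44. Targets of p53 rose in 6 of 18 and fell in 5 (adjusted p = 0.589), GADD45A by 0.92 upward, and 3 fell without DETA/NO library 1 and 2. G2/M genes rose in 9 of 24 and fell in 8 (adjusted p = 0.589), but in 4 without DETA/NO library 3 and 5 without untreated library 2. S phase genes rose in 5 and fell in 5 of 25 (adjusted p = 0.589), with MCM6 at -0.41, and 3 rose without untreated library 1. NF-kB targets rose in 9 of 20 and fell in 3 (adjusted p = 0.114 in camera and 0.000839 in fry), TNFAIP3 by 0.89 and CXCL8 by 0.70, and 5 rose without DETA/NO library 1 and 2. Iron handling genes rose in 4 and fell in 5 of 18 (adjusted p = 0.135 in camera and 0.000839 in fry), and TFRC rose by 0.14 (0.06 without DETA/NO library 3, adjusted p = 0.158). Without untreated library 1 or DETA/NO library 1 and 2, 2 iron genes rose. Of 18 genes of nitric oxide synthesis and signalling, 5 rose and 4 fell (adjusted p = 0.823), and 3 rose without DETA/NO library 1 and 2. NOS3 had 3.55 ± 3.03 and 33.7 ± 18.1 normalized reads, and NOS2 was listed at 0 in all but DETA/NO library 1 and 2, with 1.11. Immediate early genes rose in 5 and fell in 5 of 17 (adjusted p = 0.135), with FOS at -0.81. That list had an adjusted p of 0.0471 without untreated library 1 and 0.00732 without DETA/NO library 3, where 3 rose, and 3 fell without untreated library 2 or DETA/NO library 1 and 2. Among genes with GC and length values it had 0.0828 before and 0.0198 after those trends were removed. Stemness genes rose in 6 and fell in 4 of 13 (adjusted p = 0.967), apoptosis regulators rose in 7 and fell in 7 of 22 (adjusted p = 0.823), and nuclear-encoded respiratory chain genes rose in 3 and fell in 5 of 28 (adjusted p = 0.967). Apoptosis regulators fell in 4 without untreated library 1 or DETA/NO library 1 and 2 and in 3 without DETA/NO library 3. Respiratory chain genes fell in 3 without untreated library 1 or DETA/NO library 3, in 2 without DETA/NO library 1 and 2 and in 8 without untreated library 3. Glutathione and thioredoxin genes rose in 1 and fell in 5 of 16 (adjusted p = 0.135 in camera and 0.0123 in fry). Of 6 tested genes of the list of metallothioneins and the zinc response, 1 rose (adjusted p = 0.554 in camera). Without untreated library 3, 2 rose in each of these 2 lists, and 0 metallothionein and zinc response genes rose without untreated library 2. Nuclear long noncoding RNAs rose in 3 and fell in 3 of 8 (adjusted p = 0.967). Markers of other cell types that passed the filter were 4 fibroblast genes (3 rose), 4 immune genes (2 rose, 1 fell), 7 endothelial genes (3 rose; adjusted p = 0.135 in camera and 0.00154 in fry) and 3 adipocyte genes (1 rose, 1 fell, and 0 fell without untreated library 2 or 3 or either DETA/NO library). Adjusted over the list alone, these lists had the same counts, with some exceptions. Among them were 8 m6A readers higher, 7 p53 targets higher and 6 lower, and 6 S phase genes higher and 6 lower. The others were 3 respiratory chain genes lower, 4 NF-kB targets lower, 0 metallothionein and zinc response genes higher, 6 iron genes lower and 4 fibroblast genes higher. The reference genes GAPDH and ACTB rose by 0.22 and 0.16, and ACTB by 0.43 under quantile normalization.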

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

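In this part, the tests of whole overlap and of the lower DETA/NO library were chosen after the result was seen, as were LYZ and the genes at 0 named here; the other tests were written before. RPL15, a ribosomal protein gene that every cell uses, was listed at 0 in every library with 100% of its span overlapped. LDHB, with 96% of its span overlapped, was also listed at 0 in every library. Of protein-coding genes wholly overlapped by other genes' spans, 97.4% were at 0, against 14.2% of genes overlapped nowhere, 1.7% of those overlapped up to 50% and 21.95% of those overlapped further but not wholly, so the share did not rise steadily with overlap. The share was 98.0% where the overlap was on the opposite strand alone, which argues against strand-aware counting, and 98.2% where no exon overlapped, which argues against counting over exons. Of 73 list genes at 0, 72 had 1 position, and of these 50 were wholly overlapped, but SDHA and PRDX6 were overlapped nowhere, and overlap does not account for their 0. For the wholly overlapped genes, counting over whole gene bodies without strand, with reads dropped where genes overlap, stays open as an explanation; a value of 0 may then not speak to expression, and no biological explanation was tested.

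Interferon-stimulated genes were higher in DETA/NO and unequal between its libraries, with all 20 higher in library 1 and 2 than in library 3. In the lower library 100% of the 20 genes still lay above all untreated libraries, which argues against a rise carried by 1 library. Of 14 immune markers 4 passed the filter, of which PTPRC rose by 1.33 to 33.8 and CSF1R by 0.18, but CD14 fell by 1.15, and LYZ, with 12% of its span overlapped, had 2.22 and 2.85 normalized reads in the DETA/NO libraries, which argues against immune cells as the source. A response of the cells that differs in size between cultures stays open as a hypothesis, and the 2 libraries are too few to test it.

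Ribosomal protein genes were higher together by a median of 0.13 on the log2 scale. After a trend with GC content and gene length was removed, for 41 of 41 genes, the median was 0.113 and the camera adjusted p 3e-05. Before that removal the adjusted p was 0.377 with an estimated correlation, and 19 of the genes rose without DETA/NO library 3, against 31 with all libraries. Under equal totals, TMM and quantile scaling the lowest median was 0.102. Those scalings put the median of all tested genes only between -0.0103 and -0.00342. With shifts of that size a median of 0.13 could hardly reach 0, so they cannot decide whether scaling plays a part. The median of 0.113 argues against the GC and length trend as the whole cause.

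For the 7120 calls, 1 of the 10 splits of the 5 libraries into 3 and 2 gave as many, the real one, and the highest of the others gave 0. With 10 splits the share is never under 0.05, so the splits are too few.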

How the results depend on the processing

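Counts of list genes without each library and list tests without the GC and length trends were chosen after seeing the data; all other alternatives were set before. The count of genes higher and lower stayed within 1.5 times under the other pseudocounts, filters and scalings, edgeR (7001 calls, 6922 shared) and DESeq2 (5342 calls, 5323 shared, 319 genes with no adjusted p). Without a filter 581 genes were higher and 434 lower by at least 2-fold, and with a mean of at least 50 the counts were 163 and 105; the number of genes tested differs by construction. Limma without trend and robust called 2262 higher, and the cause was not tested. With an estimated correlation camera passed 0 lists higher and 0 lower, while fry passed 13 higher and 5 lower. Leaving out 1 library gave 2776 to 3573 genes higher, 2803 to 3504 lower, 269 to 376 higher and 248 to 317 lower by at least 2-fold, 10 to 11 lists higher and 4 to 6 lower; where an arm kept 1 library it was assumed to vary like the other group. EGFR had a log2 fold change of 0 under quantile normalization. That scaling gives equal values to a gene of the same rank in every library, so this 0 does not weigh against the rise. METTL3, not called, turned to 0.00118 without the shared DETA/NO library 1 and 2. The cause was not tested for METTL3. Deviations of same-numbered libraries correlated at 0.00106 and 0.0301, over 2 pairs that share the mirrored DETA/NO deviations, too few to settle pairing. With a replicate block 3143 genes were higher and 3178 lower, and the immediate early list had an adjusted p of 0.0095 (0.135 without the block). With the block, IFI44L had an adjusted p of 0.0955, IFI6 of 0.0893 and PKM of 0.11. The block paired the shared DETA/NO library with untreated library 2, which left untreated library 1 without a partner. Blocked fold changes thus rested on 2 pairs, and that of IFI44L was 3.12 both with the block and without untreated library 1. Keeping the identical files separate gave 8547 calls. Counting each named gene under each alternative as 1 case, 93 cases lost the call, 1 reversed in sign and 2810 kept the same outcome. Depth of 28897422 to 34637343 reads limits genes of low level, and the self-test recovered 70% of 1.5-fold changes. The self-test had 192 calls against 7120 in the data, so its Benjamini-Hochberg cutoff was stricter and that share does not carry over.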

Other observations

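The tests of aryl hydrocarbon receptor targets and of the chromosome 19 window as 1 gain were chosen after the result was seen, and the genes named here were chosen after their values were seen. Mitochondrial ribosomal RNAs moved apart from the mitochondrial mRNAs: MT-RNR1 and MT-RNR2 were higher, by 0.53 and 0.21 on the log2 scale. Among 1343 tested lincRNAs 168 rose and 266 fell, and among 982 antisense RNAs 99 rose and 178 fell. Among 362 genes named ZNF with a number, 58 rose and 88 fell.

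Around the amplified EGFR gene, neighbours went in different directions. VOPP1 had a log2 fold change of -0.34, SUMF2 of -0.34 and NIPSNAP2 of -0.23, while EGFR, CCT6A and PSPH had 0.15, 0.12 and 0.12. Of the neighbours examined, SEC61G and LANCL2, the nearest on each side, had -0.13 and -0.06. AC092647.5 and CHCHD2 had -0.56 and -0.01. LANCL2 and CHCHD2 were not called.

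CYP1A1 rose, and it was asked whether other aryl hydrocarbon receptor targets rose with it. Of 7 tested, 4 rose (CYP1B1 by 0.85, TIPARP by 0.46, ALDH3A1 by 0.59 and LRAT by 0.35), but 2 were lower, NQO1 and NFE2L2, which argues against a uniform rise of these targets.

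Transcripts with more m6A consensus motifs per kb of 3' UTR were tested for a change in one direction. A motif count is not a measure of methylation, which these libraries do not give. Across 11652 genes, which are not independent replicates, Spearman's rho with the log2 fold change was 0.0151 after GC and length trends were removed (permutation p = 0.109), under the 0.1 set beforehand as the smallest size of interest.

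Selection of cells with other copy numbers over the 10 days was tested in windows of 20 neighbouring genes. The largest window median was 0.455, on chromosome 19 from 42325609 to 43998325. It was 2.27 times the size that 1 in 1000 shuffled windows exceeded, 0.201, and the largest of 1000 shuffles was 0.452. The window median met the bound set beforehand, narrowly above the largest shuffle, while the median of the shuffle maxima was 0.235. Selection may thus contribute. Neighbouring genes regulated together would give the same result. Against a gain spanning the whole window, 7 of its 20 genes lay below 0.5 times its median by more than 2 standard errors, among them XRCC1 (0.00) and SMG9 (-0.03), beside PLAUR (0.91), LYPD5 (1.09) and ZNF404 (1.43). A gain of part of the window stays open.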
